A study of Mus musculus with 16 samples.

How the data were processed

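Each sample was 1 two-colour array on which tail DNA of 1 animal and DNA of 1 reference male were labelled with Cy5 and Cy3. Groups were taken from the sample titles, which name the father, the mother and F1 animals 1 to 6 of 1 family. Every animal had 2 arrays with exchanged dyes, which hybridise the same 2 DNA extracts and were counted as 1 replicate. The arrays lay on 4 slides, with the parents on slide 1, F1 animals 1 and 2 on slide 2, 3 and 4 on slide 3, and 5 and 6 on slide 4, and were scanned on 2 days.

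Per the file headers, images were read with Agilent Feature Extraction 10.7.1.1, whose protocol subtracted background, removed spatial trends and normalised the dyes linearly to give the processed red and green intensity of each spot. The deposited LogRatio column is the log10 of red over green processed intensity, and the deposited error column is the error of that ratio. The deposited series matrix holds log2 ratios; set against the scanner ratios, their scale was log2, their offset was at most 0.02 and no step of recentring is stated. By the dyes in the labels, 14 of its columns run as animal over reference and 2, both of F1 animal 5, as reference over animal. Its column medians, with the animal in Cy3 and in Cy5, were 0.01 and 0.00 for the father, 0.01 and 0.01 for the mother, −0.00 and 0.00 for F1 animal 1, 0.01 and 0.01 for animal 2, −0.00 and −0.00 for animal 3, −0.00 and 0.02 for animal 4, 0.00 and −0.01 for animal 5 and 0.01 and 0.01 for animal 6. The genome build in the headers is mm9, and probe positions are those of the files. The only annotation at hand names GRCm38, a different build, so no gene was assigned to a region, and the gene lists fixed beforehand could not be evaluated.

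Log2 ratios were computed from the processed intensities, turned to animal over reference by the dyes in the labels, centred on the median of each array, and averaged over the spots of a probe and then over the 2 orientations. No loess or quantile step was applied, because probes can truly shift. Control spots and spots marked as outliers were left out, and no spot was saturated. Ratios of different animals in the same orientation correlated with a median r of 0.54 (animal in Cy5) and 0.51 (animal in Cy3) across probes. In opposite orientations the median r was −0.01 (−0.39 to 0.27). The drop shows a shared dye effect, which cancels in the mean of both orientations. A dye effect alone would give a clearly negative median in opposite orientations, so part of what the animals shared was not dye and remains in the mean. Within an animal the 2 orientations correlated with r of −0.17 (F1 animal 1) to 0.50 (F1 animal 3) across probes.

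Regions were called on the 19 autosomes by an interval score, the sum of log2 ratios over an interval divided by the spread between neighbouring probes and by the square root of the number of probes, in runs with no gap above 100 kb. A region needed a score of at least 6, at least 3 probes and a mean of at least 0.25 in size in the average and in each orientation with the same sign. A parent was counted as carrying a region with a mean of at least 0.25 in the same direction in both orientations. Calls of one direction that shared a probe were merged, and carriers of the merged region were scored by the same rule over the probes found in at least 50% of the merged calls. The same calling was run on the contrast of the orientations, which keeps the shared dye effect, so its counts do not estimate the false calls in the average. On simulated data with the real probe layout of 149792 autosomal probes and the spread of F1 animal 3, 90.0% of inserted 3-probe regions of 0.4 in size and all larger ones were recovered, with 0 false regions; at the spread of F1 animal 1 all were recovered. The simulated noise was independent between probes, which the real noise need not be.

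Counts per animal were compared between F1 and parents by an exact permutation test. F1 values per probe were tested against 0 with limma 3.58.1 in R 4.3.3, with a prior variance following the mean log2 intensity of a probe and Benjamini-Hochberg adjustment at 0.05. A trend over the mean log2 ratio was kept as an alternative and gave 1260 higher and 1030 lower probes on the real data. With the trend over intensity, simulation on 149395 probes recovered 64% of 100 probes shifted by 0.25 in size and 88% of 100 shifted by 0.5, with 5 false calls. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0. The number of arrays limits the precision.

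Before the data were examined, it was fixed that the text would name the 10 F1 regions carried by neither parent with the highest scores and the 20 regions carried by a parent or by all animals with the largest mean log2 ratio in the highest-scoring carrier. Regions named outside this rule were chosen after their values were seen. These are the regions of at least 20 probes on chromosomes 4, 14 (53387742 and 54289537) and 15, the short regions on chromosomes 13 and 19, and those listed among the results for a closer look that the rule does not take. Alternatives were normexp background correction with an offset of 50, made on median signals because the files hold no mean signals, the deposited ratios, the matrix, loess, other thresholds for score, probes and mean, probe weights, no gap limit, each orientation called alone, removal of dim probes, and subtraction of a running median over 1 Mb in place of a correction for base composition, which needs a genome. Carriers were scored at 0.25 under all alternatives that change only the calling.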

Results

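DNA from the tails of 1 mouse family was compared with DNA of 1 reference male from the same colony by array comparative genomic hybridisation, which measures the copy number of a sequence as the ratio of 2 fluorescent signals. The family consisted of a father, a mother and 6 F1 offspring of the inbred strain C57BL/6. Each of the 8 animals was hybridised on 2 arrays with the dyes exchanged, giving 16 arrays on 4 slides, and the 2 arrays of an animal were averaged and counted as 1 sample. The series is about offspring of male mice exposed to 1 mGy of gamma rays per day for 400 days; its title and its design text disagree on whether this father was irradiated, and no comparison below uses the exposure. The array carried 149843 distinct probes with a median distance of 88 bp between neighbouring probe starts, placed around positions that an earlier screen of this same family had selected, so the regions are not an unbiased sample of the genome. On every array at least 99.5% of the probes were well above background in each channel, and the spread between neighbouring probes was 0.10 to 0.14 on the log2 scale. After averaging, this spread was 0.04 to 0.05 in the father and in 5 F1 animals, 0.08 in the mother and 0.09 in F1 animal 3. Single animals were not repeated, so the error given for a region is the difference between its 2 dye orientations. Coordinates are those of mm9, and no annotation of that build was used, so regions are given by position without gene names.

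The sex chromosomes were used to check the labels. Median log2 ratios on X were 0.87 in the mother, 0.95 in F1 animal 5 and 0.93 in F1 animal 6, against −0.02 to 0.02 in the father and the other 4 F1 animals. On Y, where the array held 3 probes, the medians were −2.54 in the mother, −2.77 in F1 animal 5 and −2.71 in F1 animal 6, and −0.05 to 0.00 in the rest. The values of F1 animal 5 follow the dyes named in the labels; the deposited matrix of log ratios holds both arrays of this animal with the opposite sign.

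The first question was whether F1 animals carried regions that neither parent carried. Among the regions of at least 20 probes, 2 events stood out by their score. A loss at chromosome 14: 38288894 to 38431231, covering 142 kb and 869 probes, was present in F1 animal 5 with a mean log2 ratio of −0.79, and was −0.81 and −0.76 in the 2 dye orientations. The father had 0.02 over the same probes, the mother −0.00 and the other F1 animals −0.00 to 0.05. The neighbouring probe before the loss lay 76 bp away and the next probe after it 8823 bp away.

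A gain at chromosome 12: 82587634 to 83527347, covering 940 kb and 6177 probes, was present in F1 animals 2, 4 and 5 with mean log2 ratios of 0.40, 0.49 and 0.43. F1 animals 1, 3 and 6 had −0.00, −0.05 and −0.02, and the father had −0.01. Calls of 6 animals were merged into this region, and 3 of these animals carried it by the rule. Calls of at least 20 probes came only from F1 animals 2, 4 and 5. The mother had 0.16, with 0.16 and 0.15 in the 2 orientations, which is below the minimum of 0.25 set for carrying a region, and the gain was therefore counted as carried by neither parent. With the minimum for parents lowered to 0.1, the mother counted as a carrier. In 10 equal windows across the region the mother lay between 0.14 and 0.17. The last probe before the gain lay 537540 bp away, so its left boundary is known only to that distance, and the right boundary lay within 269 bp.

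**Figure D1:**
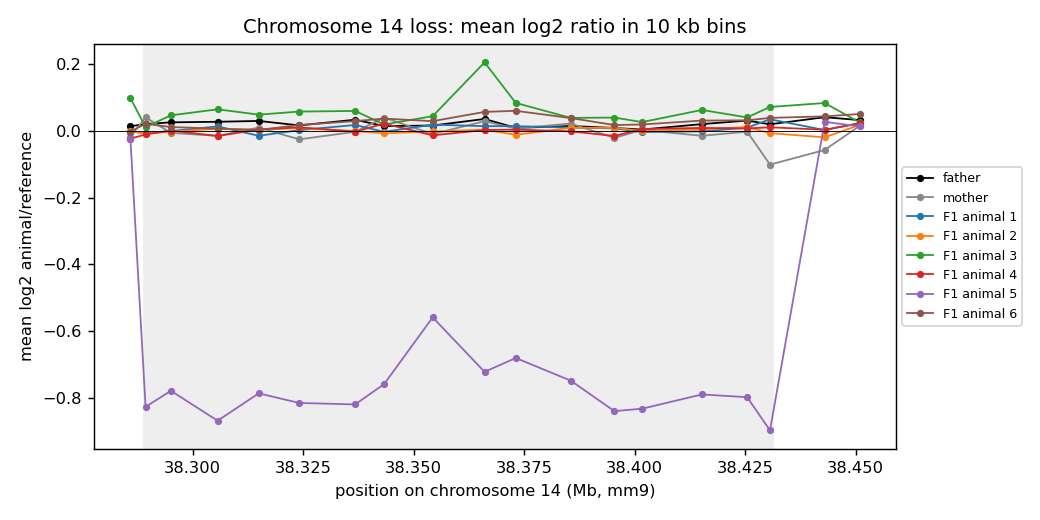
Mean log2 ratio of animal over reference (vertical axis) against position on chromosome 14 in Mb (horizontal axis) for the 8 animals, in bins of 10 kb that are split at the boundaries of the called loss (grey). F1 animal 5 lies far below 0 inside the region, where its mean is −0.79, and near 0 on both sides.

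**Figure D2:**
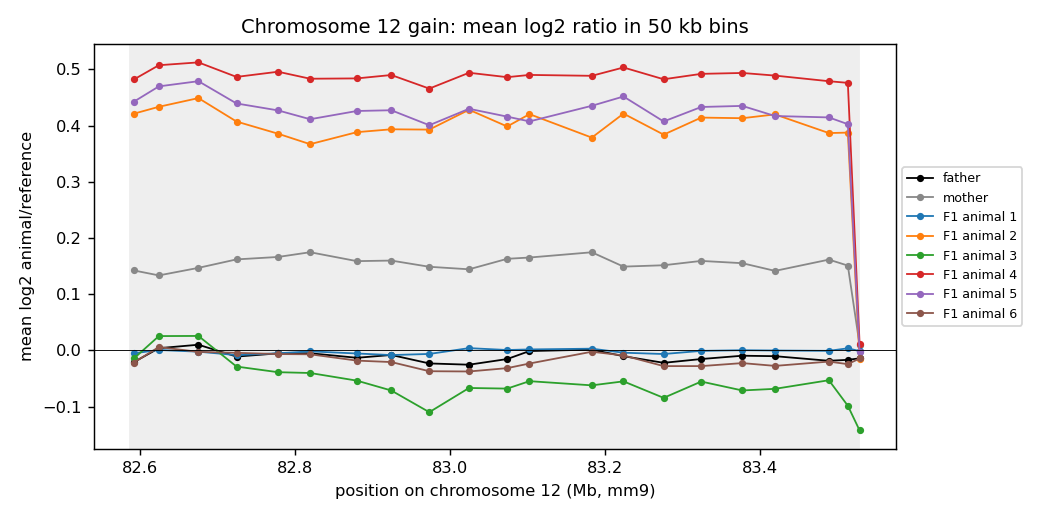
Mean log2 ratio of animal over reference (vertical axis) against position on chromosome 12 in Mb (horizontal axis) for the 8 animals, in bins of 50 kb; grey marks the called gain. F1 animals 2, 4 and 5 lie at 0.40 to 0.49 on average, the mother at 0.16, and the other 4 animals near or slightly below 0.

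Over all sizes, the 6 F1 animals had 891 called regions, of which 638 were carried by neither parent, 172 by the mother alone, 59 by the father alone and 22 by both. F1 animal 3 held 422 of the 638 and 107 of the 172, and F1 animal 2 held 45 of the 59. Without F1 animal 3 there were 216 carried by neither parent and 65 by the mother alone, and without F1 animal 2 there were 14 carried by the father alone. F1 animals 5 and 6, the only F1 animals with high X and low Y ratios, held 28 and 34 of the 65. For these, sex and inheritance from the mother cannot be told apart by the carriers. The classes also depended on the rule for parents: with a minimum of 0.1, 390 were carried by neither parent and 387 by the mother alone, and with a call of the parent's own in place of the minimum, 479 were carried by neither and 325 by the mother alone. The highest-scoring regions of F1 animal 3 carried by neither parent were gains of 1 to 2 kb at chromosome 15: 63115872 to 63117598 with 0.84, chromosome 5: 50895206 to 50896827 with 0.77, chromosome 17: 78326914 to 78328872 with 0.62, chromosome 3: 78511236 to 78512574 with 0.74 and chromosome 14: 13217381 to 13219614 with 0.66; the mother had 0.03, 0.10, 0.15, 0.24 and 0.13 there. The remaining region among the 10 with the highest scores was a gain of 0.27 in F1 animal 6 at chromosome 10: 52261341 to 52265658, where F1 animal 5 had 0.28 and the mother 0.26. In the mother the orientation with the animal in Cy5 fell just short of 0.25 over these 36 probes, with 0.24. The father and the other F1 animals had −0.02 to 0.01. The animals with 0.26 to 0.28 were exactly those with high X and low Y ratios, so this gain may follow sex and is no clear case of a new F1 region. No test across animals applies to a region of a single animal.

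The second question was which parental regions reached the F1 animals. A gain at chromosome 4: 101109089 to 101270967, covering 162 kb and 1333 probes, had a mean log2 ratio of 0.84 in the father and 0.02 in the mother. All 6 F1 animals carried it, with 0.45 ± 0.03 (SD, n = 6) and a range of 0.41 to 0.50. A region of 70 probes at chromosome 2: 70079530 to 70086801 was also carried as a gain by the father and all 6 F1 animals. The mother had 0.07 over the 70 probes and did not carry it, although a gain call of her own was merged into it. In 36 of its probes the reference was well above background on every array; over these the father had 2.15 and F1 animals 1 to 6 had 1.05, 0.94, 1.92, 1.89, 1.21 and 1.20. In the other probes the ratio is only a bound on at least 1 array. These F1 values went with the slide, each slide holding 1 consecutive pair of F1 animals. On the arrays of the mother the median signal of the region was 63.8 to 64.1 units in the reference and 65.1 to 70.2 in the mother, while on the arrays of the other 7 animals it was 46.5 to 108 in the reference and 622 to 1070 in the animals. Over whole arrays the median background-subtracted signal was 540 to 1143 in green and 754 to 1597 in red. The called gain thus reflects a low signal in the reference, shared by the mother, more than a high signal in the other animals. A loss of 5 probes at chromosome 19: 27013066 to 27013509, singled out after its values were seen, was present in the father with −0.74 and in F1 animals 1, 2 and 5 with −0.67, −0.60 and −0.73, while the mother and the other F1 animals had −0.02 to 0.06.

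Among the regions carried by the mother and not by the father, a loss at chromosome 3: 25416456 to 25456288 was the strongest. It covered 39.8 kb and 149 probes, with a mean log2 ratio of −1.93 in the mother, −1.90 in F1 animal 5 and −1.90 in F1 animal 6. The father and F1 animals 1 to 4 had −0.01 to 0.02. The carriers were the same 3 animals whose X ratios were high and Y ratios low, so the carriers alone cannot separate sex from inheritance. Over the chromosome 4 gain all F1 animals lay between the parents. Here F1 animals 5 and 6 had the mother's full value and F1 animals 1 to 4 that of the father, which argues against autosomal inheritance from the mother. In all, 25 merged regions on 12 chromosomes were carried by exactly the mother and F1 animals 5 and 6, 22 of them losses. No other set of 3 animals carried more than 2. Of the 25, 22 had 3 probes, and in only 5 did the median over the probes also pass 0.25 in all 3 animals. For example, the loss at chromosome 3: 132549293 to 132549686 had a mean of −1.04 but a median of −0.10 in F1 animal 6. Of the 20 parental regions selected by size, 16 were gains of 3 to 10 probes carried by the mother and F1 animal 3, with 0.29 to 0.50 in the mother and 0.52 to 1.06 in F1 animal 3.

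**Figure D3:**
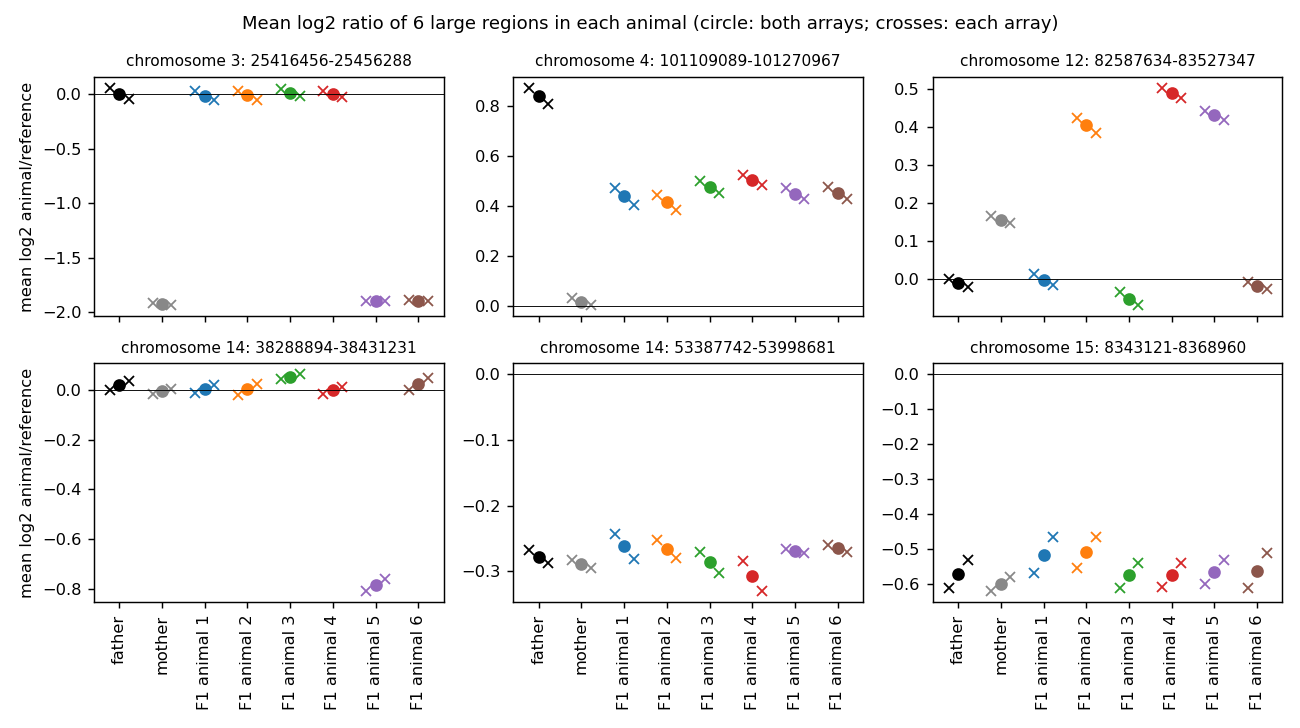
Mean log2 ratio of animal over reference (vertical axes) of the 6 merged regions with at least 100 probes, for each of the 8 animals (horizontal axis); circles are the mean of both arrays and crosses are the single arrays. The father lies at 0.84 and the F1 animals at 0.41 to 0.50 on chromosome 4, and the mother and F1 animals 5 and 6 lie near −1.9 on chromosome 3.

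Regions carried by every animal came next, since the single reference animal is then the one that may differ. A loss at chromosome 15: 8343121 to 8368960, covering 226 probes, was present in all 8 animals, with −0.57 in the father, −0.60 in the mother and −0.55 ± 0.03 (SD, n = 6) in the F1 animals. A gain of 3 probes at chromosome 13: 95705166 to 95707524 was the other region carried by all 8. A shallower loss at chromosome 14: 53387742 to 53998681, covering 428 probes, had −0.28 in the father, −0.29 in the mother and −0.28 ± 0.02 (SD, n = 6) in the F1 animals. F1 animal 1, with −0.26 on average, fell short of 0.25 in 1 orientation and was not counted as a carrier. It nevertheless had its own calls inside this loss, of 388 and 26 probes, each with a mean of −0.28.

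The F1 animals were then compared with the reference probe by probe. Of 149395 autosomal probes tested with limma, 1322 were higher and 911 lower in the F1 animals at a Benjamini-Hochberg adjusted p of 0.05, and 16180 had an unadjusted p under 0.05. The chromosome 4 gain held 1254 of the higher probes and the chromosome 2 gain 58. The shared losses held 369 (chromosome 14: 53387742 to 53998681), 219 (chromosome 15) and 29 (chromosome 14: 54289537 to 54300162) of the lower probes. No probe of the chromosome 12 gain or the chromosome 14 loss of F1 animal 5 passed; each was missing from at least 3 of the F1 animals. Outside merged regions of at least 20 probes, 10 of 139580 probes were higher and 294 lower, with a median absolute log2 ratio of 0.25. The test covers differences from this 1 reference animal only, and neighbouring probes are not independent.

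The number of called regions differed widely between animals. F1 animal 3 had 536 regions, 486 of them gains, and the mother had 331, of which 288 were gains. F1 animal 5 had 146, the father 93, F1 animal 2 had 73, F1 animal 6 had 62, F1 animal 4 had 58 and F1 animal 1 had 16. The counts of single animals changed by more than 1.5 times under several alternatives; that of F1 animal 3 did so only when calls were made anew with a minimum of 20 probes, which gave 238, while 26 of its 536 main regions had that many. Most were short, and 1252 of the 1315 regions had fewer than 20 probes. The same calling on the contrast of the 2 dye orientations, which removes the difference between animal and reference but keeps the dye effect that the average cancels, gave 507 regions in the 8 animals; it exceeded the real count in F1 animals 1, 2 and 6, with 78, 91 and 91 regions, and was 13 in F1 animal 3. Of the 1315 regions 63 had at least 20 probes, and of the 507 in the contrast 5 did. Permuting the probe order, which keeps the values of probes in real regions, gave 3438 regions, of which 128 had at least 20 probes, 37, 35 and 48 of these in F1 animals 2, 4 and 5; in F1 animal 3 it gave 335 and in the mother 187. The F1 animals had 148.5 ± 194 regions (SD, n = 6) and the parents 212 ± 168 (SD, n = 2), a difference of −63.5 with p = 0.821 in a two-sided exact permutation test over 28 splits, whose smallest possible p is 0.0357. The difference was −141 without F1 animal 3 and −37.0 without F1 animal 1, and it became 20.2 with probes weighted by their deposited error and 39.5 with calls made anew with 20 probes. Under the other alternatives it lay between −72.3 with loess and −4.83 with a minimum mean of 0.35, and no exact p was below 0.0952. Parents and offspring lay on different slides, so slide and generation cannot be told apart.

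**Figure D4:**
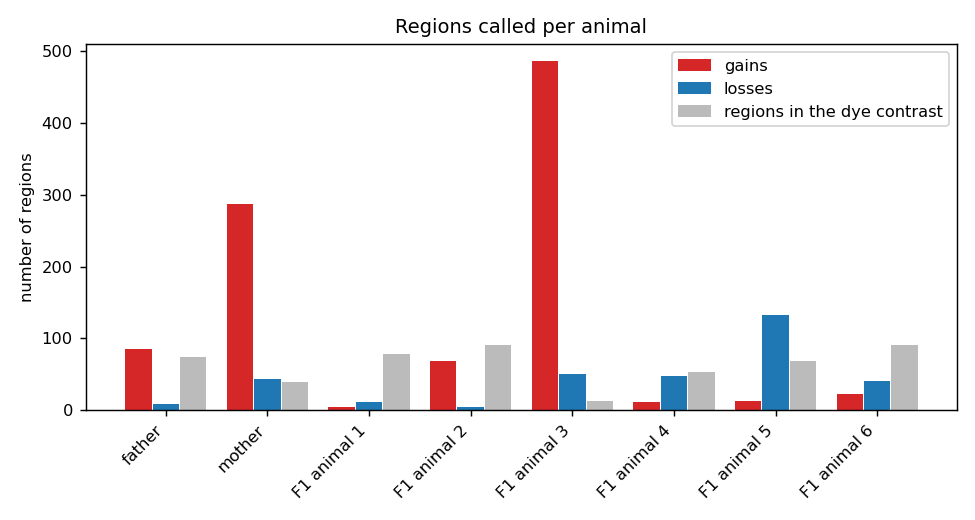
Number of gains (red), losses (blue) and regions called in the contrast of the 2 dye orientations (grey) on the vertical axis, for each of the 8 animals on the horizontal axis. F1 animal 3 with 486 gains and the mother with 288 exceed their contrast counts of 13 and 39, while the other animals lie closer to theirs.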

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

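Except for that on probe lengths, the tests in this part were chosen after the result was seen. The 6 F1 animals were searched for a value far from the other 5 in 52 results, and 39 had one; chance gives about 1 in 20, but the regions had been called because an animal departs from the reference, so the number is no independent evidence.

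Only F1 animal 5 carried the loss on chromosome 14, with −0.79, and it lay far from the other F1 animals. A foreign sample without the paternal chromosome 4 gain is argued against, since F1 animal 5 had 0.45 there, within the 0.41 to 0.50 of its siblings. A sample of another mouse that carries this gain at a similar level is not excluded. The loss did not rest on a few probes, since 89.0% of the 869 probes lay below −0.4. A loss that arose in a parental germ cell, in the early embryo or in the tail tissue may account for it. These origins are hypotheses found on these data, were not tested, and stay open. The sample was hybridised from a single extract, and an error in that extract was not tested.

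F1 animal 3 had 536 called regions against 16 to 146 in the other F1 animals, 26 with at least 20 probes against 4 to 9, and a spread between neighbouring probes of 0.0911 against 0.0402 to 0.0529. In 34 regions its mean log2 ratio, 0.35 to 1.06, lay far above the others, which ranged from −0.39 to 0.16. By start position these were 0.55 at 43394743, 0.44 at 63567307 and 1.04 at 146188721 on chromosome 1, 0.35 at 131289276 and 0.42 at 169628173 on chromosome 2, 0.60 at 109266977 on chromosome 3, 0.43 at 89083812 on chromosome 4, and 0.43 at 9809890, 1.04 at 67159722 and 0.97 at 127019786 on chromosome 5. On chromosome 6 they were 0.62 at 35962711, 0.61 at 98384197 and 0.53 at 144340075, on chromosome 7 1.01 at 76784231 and 0.99 at 99284904, on chromosome 9 0.42 at 80023347 and 1.00 at 81452888, on chromosome 10 0.98 at 90517255, and on chromosome 11 0.55 at 45162030 and 0.97 at 13153567. On chromosome 12 they were 1.06 at 111242302 and 0.96 at 46420118, on chromosome 13 0.54 at 48136605 and 0.54 at 117034211, on chromosome 14 0.66 at 13217381 and 0.59 at 93754028, on chromosome 15 0.41 at 99038165, 1.03 at 40387458 and 1.00 at 48654366, on chromosome 16 0.58 at 95474557 and 0.97 at 69085118, on chromosome 17 0.60 at 62872304 and 0.62 at 78326914, and on chromosome 18 0.41 at 52879180.

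The short gains of F1 animal 3, 484 on 19 chromosomes with a median length of 824 bp, had a median log2 ratio of 0.68 in this animal, 0.18 in the mother and −0.12 to 0.07 in the other 6; 255 of the 484 were also called as gains in the mother. Dye bias and noise that differ between its 2 arrays are argued against by the 13 regions in its dye contrast against 536 called, inheritance of the mother's copy number as the whole cause by the 288 short gains called in the mother, where F1 animal 3 had a median of 0.80 and she had 0.39, a difference of 0.41, and the slide by F1 animal 4 on the same slide, which had −0.12. Permuting its probe order gave 335 regions, none with at least 20 probes, so for part of the short regions chance neighbours among probes that deviate on both arrays are not excluded. Base composition was read only from probe length. Full-length probes made up 56.6% of the probes in these gains and 51.0% of the other autosomal probes. The difference of 5.66 percentage points was below the 10 set beforehand. Probe length is only an indirect reading of base composition, so this test cannot decide on it. The share was also raised in the short gains of the father, with 57.8%, so a part played by base composition is not excluded. A property of the single DNA preparation, such as its fragmentation, may remain as a source and was not tested.

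The loss on chromosome 14 at 54289537 was lowest in F1 animal 4, with −0.28 against −0.24 to −0.23 in the other F1 animals. The father had −0.27 and the mother −0.26. The gap to the next F1 animal was below the spread between orientations of named regions (0.06).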

How the results depend on the processing

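The alternatives with a minimum of 20 probes, the parental classes without 1 F1 animal, the matrix with its deposited signs, the calls without the mother and F1 animal 3, the X and Y probes, and the variance trend over the log2 ratio were chosen after seeing the data. Normexp, the deposited ratios, the matrix turned by its direction, no gap limit, X and Y included, a score of 8, each orientation called alone and removal of dim probes left the counts summed over animals within 1.5 times the main ones. Elsewhere the cause of a change was not tested unless it follows from the setting. Counts of all regions (1315), of F1 regions carried by the father alone (59), the mother alone (172) and neither parent (638) and of merged regions (846) became 2356, 89, 265, 1321 and 1431 with a minimum mean of 0.15, and 609, 21, 110, 341 and 460 with error weights. With a minimum mean of 0.35 there were 815 regions, 29 carried by the father alone and 398 by neither. With 5 probes there were 873, 20 paternal and 102 maternal. With calls made anew with 20 probes there were 277 regions, 12 paternal, 3 maternal, 13 of both parents (22) and 239 of neither, and 242 merged. Without the calls of the mother and F1 animal 3 there were 448, with 65 maternal, 216 of neither and 313 merged. Maternal regions were 387 and those of neither parent 390 when a parent needed 0.1, and maternal ones 325 when it needed its own call; paternal ones were 107 after the running median. Merged regions carried by all 8 animals (2) numbered 4 with loess, 6 at a mean of 0.35, 1 with error weights, 1 with 20 probes and 0 with the deposited signs. Leaving out 1 F1 animal gave 14 to 57 paternal regions, 65 to 172 maternal, 17 to 20 of both and 216 to 630 of neither, with 14 paternal without F1 animal 2 and 65 maternal and 216 of neither without F1 animal 3. Counts of single animals (father 93, mother 331, F1 animals 1 to 6 16, 73, 536, 58, 146 and 62) moved as follows. With normexp F1 animals 1, 2, 4 and 5 had 7, 39, 12 and 67, and with loess F1 animal 4 had 36. In the order father, mother and F1 animals 1, 2, 4, 5 and 6 they were 27, 211, 8, 15, 21, 74 and 31 with 5 probes, 35, 176, 6, 20, 16, 58 and 36 at a mean of 0.35, and 15, 107, 5, 10, 5, 22 and 8 with error weights. At a mean of 0.15 the father had 259 and F1 animals 1, 2, 4, 5 and 6 had 83, 229, 224, 335 and 208. With each orientation called alone the father had 57, the mother 205 and F1 animals 2, 4, 5 and 6 had 46, 32, 78 and 34. With the running median F1 animals 1 and 2 had 28 and 135. With calls made anew with 20 probes the father had 5, the mother 5 and F1 animals 1 to 6 had 5, 5, 238, 4, 9 and 6. The contrast of orientations gave 5 regions in place of 507 when called anew with 20 probes, and permuting probe order gave 3438. The difference of F1 and parents turned to 20.2 (exact p = 0.964) with error weights and 39.5 (exact p = 0.643) with 20 probes, was −33.2 with a score of 8, −22.0 without the calls of the mother and F1 animal 3, −16.0 with each orientation called alone, −13.2 with 5 probes and −4.83 at a mean of 0.35 against −63.5, and ranged from −141 to −37.0 when 1 F1 animal was left out. Leaving out 1 F1 animal gave 1269 to 1339 higher and 830 to 970 lower probes in limma. The probes with an unadjusted p under 0.05 (16180) then numbered 9593 without F1 animal 5 to 21060 without F1 animal 3. Testing against 0.25 gave 995 higher and 291 lower. The SD of all probes, 0.18, replaced a median neighbour spread of 0.11 per array. With normexp, X was 0.82 in F1 animal 5 and 0.85 in F1 animal 6, and Y was −1.08 in the mother, −1.54 in F1 animal 5 and −1.45 in F1 animal 6. With the deposited signs F1 animal 5 turned to −0.43 on chromosome 12, 0.79 on chromosome 14, −0.45 on chromosome 4, −0.95 on X and 2.77 on Y, by construction. Of 192 values of named regions, 167 moved by less than the spread between orientations (0.06), 22 moved by more and 3 changed sign. The chromosome 14 loss and the chromosome 12 gain were called in the main carriers under 15 of 17 alternatives. Several of the 17 could hardly change these calls, such as the deposited ratios, the turned matrix, a score of 8, a minimum of 5 or 20 probes, and X and Y included. The running median removed both and the chromosome 4 gain. A median over 1 Mb can follow regions this long and densely probed, so that alternative cannot decide on them. No paired analysis was possible, because replicate numbers only count animals within a group and pair no F1 animal with a parent. Dim reference signal limits the chromosome 2 gain, whose father value was 2.29 with normexp against 3.70 over all probes.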

Other observations

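Of the tests in this part, that on the chromosome 4 gain was chosen after the result was seen, as was the search over the short gains of the father. A second set of short gains was shared by the father and F1 animal 2. The father had 83 gains of fewer than 50 probes, on 19 chromosomes with a median length of 217 bp, and over these the median log2 ratio was 0.37 in the father, 0.30 in F1 animal 2, 0.14 in F1 animal 6 and −0.08 to 0.02 in the other 5 animals. Of the 83, 45 were also called in F1 animal 2 and 5 in F1 animal 3. The 83 were chosen by the father's own values, so his median there is high by selection. With a minimum of 5 probes, F1 regions carried by the father alone fell from 59 to 20. Of all 1315 regions, 199 had a median over probes under 0.25 in size, and F1 animal 6 had 35 such regions among its 62.

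The mother's value of 0.16 over the chromosome 12 gain lay between the carriers and the non-carriers among the F1 animals. DNA of carrier offspring in the mother's sample is argued against by her 0.016 over the chromosome 4 gain, where this admixture would give 0.16. A few probes as the source are argued against by 0 of 10 windows under 0.05. In 226 blocks of 617 consecutive probes outside regions of at least 20 probes, her highest mean was 0.053 against at least 0.14 in the windows. The probes lay in 4466 runs separated by gaps above 100 kb, so blocks of this length generally join distant places. The blocks therefore cannot decide on noise of her arrays over a continuous, densely probed stretch, which stays open. Her mean inside the region exceeded that of the 33 flanking probes by 0.15, but in F1 animal 3, which did not carry the gain, it did so by 0.09. On the linear scale her excess was 35.2%, 28.1% and 32.7% of that of F1 animals 2, 4 and 5. A candidate explanation is that a share of the mother's cells carried the gain and that she passed it to 3 of 6 offspring, which is a hypothesis found on these data; a second tissue of the mother was not analysed here.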
